A study of Drosophila melanogaster with 4 samples.

How the data were processed

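Binding sites of cap'n collar (CNC) were mapped by ChIP-seq, in which chromatin is crosslinked, immunoprecipitated with an antibody and sequenced. The series holds 4 libraries from adult females of Drosophila melanogaster, aged 2 to 3 days, of a strain carrying the eye and body markers y, cn, bw and sp. The 2 ChIP libraries and the 2 input libraries were grouped by their titles, which number the replicates 1 and 2 in each group. Nothing in the labels says whether replicates came from separate collections of flies.

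The values analysed are those of 1 peak list for the whole series. Per the submitters' processing notes, the reads were handled with CASAVA 1.7.0.2 and 1.7.0.3, BWA and MACS2 on the build BDGP5. Per the file header, coordinates are those of FlyBase release 5, and the caller is named as MACS. Each peak has a start, an end and 1 score given by the authors' caller. Which MACS statistic the deposited score is, what threshold was applied, how the 2 ChIP replicates were combined and how the inputs entered the calling are not given in the sources used here. The score was therefore used only within this list, to rank, describe, filter and relate peaks, and no ratio of scores is given. The list holds no value of a single library, so no spread between replicates, no ChIP-against-input test and no read depth could be given, and the depth behind each peak is unknown. All p-values below compare peaks with random placements or with other peaks of the same list. Peaks are not replicates of an experiment.

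Gene features, promoter distances, sequence motifs and gene lists were planned and not analysed here. The gene table used was of release 6, a different assembly from the list's release 5, and coordinates were not converted. No gene is assigned to any peak. Instead, as fixed before the data were examined, the 12 peaks of highest score and the 2 longest peaks are named by their release 5 coordinates, counted from 1.

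Peak lengths, scores and distances were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plotted with matplotlib 3.10.9. Tests of position used the 5 major arms, 2L, 2R, 3L, 3R and X. Spacing was the median distance between centres of neighbouring peaks, where the centre is the midpoint, since no summit is listed. It was compared with 1000 random placements of the same peaks between the first and last peak of their arm, these 2 staying in place (two-sided, smallest possible p 0.002). The density of an arm was its number of peaks per Mb of that same span, and was tested by redrawing all peaks over the 5 spans 100000 times. The alternative on sequence under peaks used 1000 redraws. Without arm lengths the plan was to give counts alone, and this density test on spans was added after the data were examined. Medians and correlations were tested by 100000 permutations of the peaks (two-sided, smallest possible p 1e-05). Tests within twentieths of the score used 10000 permutations (two-sided). Differences in score rank within pairs of neighbours were tested with 10000 shuffles or random draws (one-sided). Counts of high-scoring peaks were compared by Fisher's exact test (two-sided), and p-values were adjusted by the Benjamini-Hochberg method within each family. Dense stretches were windows of 100 kb, tested against 1000 shuffles of the distances between neighbours within an arm (one-sided). Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and take peaks as independent.

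The tests of spacing, density, medians and rank correlation, and no others, were also run on simulated data, with fewer resamples. With 1641 peaks placed uniformly, the spacing test made a call in 3 of 100 runs, and with 25% of the peaks set beside another it made a call in 100 of 100. The density test called 3 arms over 100 uniform runs, and called 2R in 93 of 100 runs when its count was raised by 30%. No density run used grouped peaks, so these runs give no error rate for peaks that lie in groups. The median test compared a smaller set of simulated values with 300 others. It made a call in 9 of 100 runs with no shift, more than the threshold of 0.05 gives on average, and in 100 of 100 with a shift of 1 SD. On 300 simulated pairs of values, the correlation test made a call in 4 of 100 runs with unrelated values and in 100 of 100 with related ones. Alternatives were the 842 and the 421 peaks of highest score, joining of peaks closer than 1 kb, other sets of sequences and other scales. Joining within 5 and 20 kb and a span from position 1 of the arm were added after the data were examined. Tests of arm density, arm medians, high scores, dense stretches, unplaced sequences and close neighbours were also chosen after seeing the data.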

Results

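The series mapped where cap'n collar binds the genome of adult female flies. Cap'n collar (CNC) is a basic leucine zipper transcription factor, the fly counterpart of the vertebrate NRF proteins, known for head patterning in the embryo and for control of antioxidant and detoxification genes. The antibody, a rabbit polyclonal, was raised against a CNC fragment. Chromatin from 2 immunoprecipitated libraries and 2 input libraries gave a single deposited list of 1684 peaks on FlyBase release 5. Values of single replicates were not used, so no value below has a replicate error, and the read depth is unknown.

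CNC peaks were short and mostly of low score, with a long tail of high scores. Together the 1684 peaks covered 1021 kb. The median peak was 439 bp long (interquartile range 298 to 717 bp), the shortest 201 bp and the longest 6723 bp. The authors' score ranged from 6.06 to 449.55, with a median of 19.8 and an interquartile range of 13.0 to 42.0. A score above 100 was reached by 178 peaks, or 10.6% of the list, and a score above 300 by 14 peaks. All 178 lay on the major arms.

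The highest score in the list, 449.55, belonged to a 1265 bp peak on 2R (5876178 to 5877442). A second 2R peak, at 5579045 to 5580770, scored 444.78 and had no other peak within 87.7 kb. The third, at 1614388 to 1621110 on 3R, scored 441.8 and was also the longest peak of the list. Its nearest neighbour lay 107 kb away. The highest-scoring X-linked peak scored 439.64 and spanned 12629110 to 12630471. The next sites were a 3R peak at 21448847 to 21450645, with a score of 381.74, and a 2L peak at 8689533 to 8694749, with a score of 378.38. On 2L, the peak at 16525420 to 16527809 scored 364.3 and the peak at 9788627 to 9791633 scored 324.45. The other 4 of the 12 highest-scoring peaks were on 3R. They lay at 19014137 to 19017196 with a score of 361.04, at 8194707 to 8196783 with 353.27, at 12902799 to 12905544 with 353.04, and at 14741026 to 14742947 with 303.77. In all, 6 of the 12 were on 3R, 3 on 2L, 2 on 2R and 1 on X. The list placed no gene at these sites, and none was assigned here.

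The longest peaks after the 3R site adjoined each other on 2L. The second longest peak of the list, 5232 bp at 8694886 to 8700117, scored 66.17 and began 136 bp past the end of the 2L peak that scored 378.38. The pair spanned 10.6 kb. Only 3 peaks of the list exceeded 5000 bp, these 2 and the 3R site, and 230 peaks exceeded 1000 bp.

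**Figure D1:**
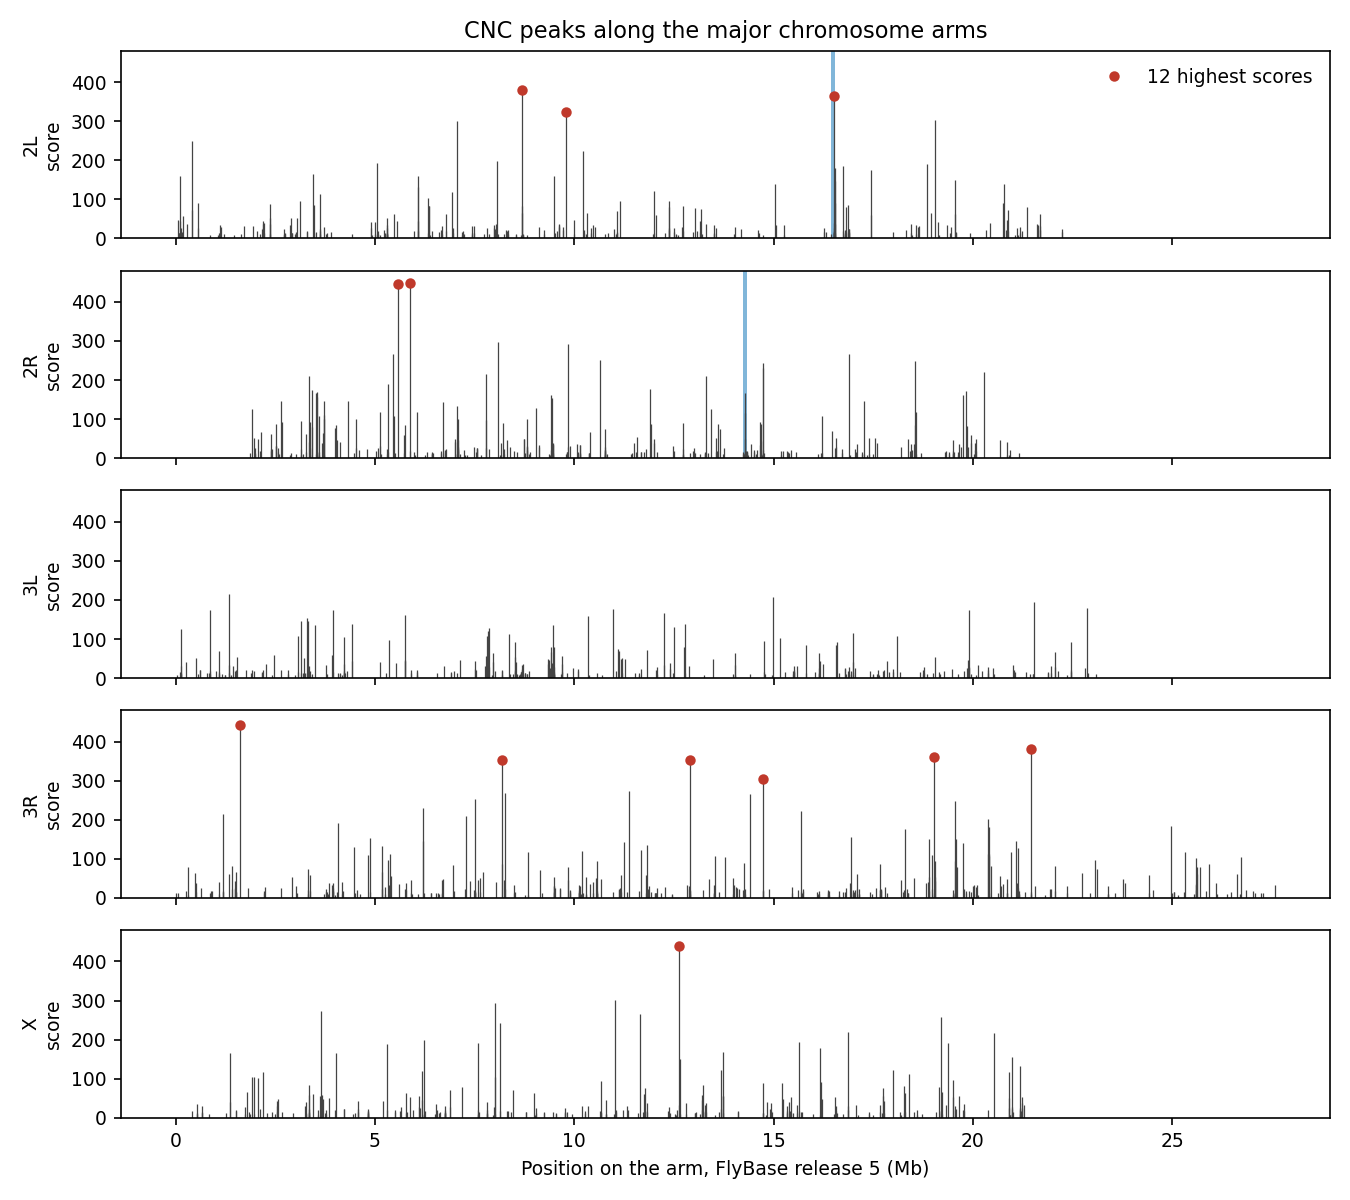
Each vertical line is a CNC peak at its midpoint on the major arms (x axis, Mb on FlyBase release 5), with the height giving the authors' score (y axis, no unit stated). Red points mark the 12 highest scores, from 303.77 to 449.55, none of which is on 3L; blue bands mark the 2L and 2R stretches with 17 and 16 peaks.

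Longer CNC peaks had higher scores. The median score was 11.5 among the 421 shortest peaks (201 to 297 bp) and 83.8 among the 421 longest (718 to 6723 bp). Across the 1684 peaks, Pearson's r was 0.76 and Spearman's rho 0.81 (permutation p = 1e-05 for both, the smallest possible). Spearman's rho lay between 0.80 and 0.84 on each of the 5 arms. These are relations across peaks of 1 list, which are not independent replicates. The same caller set both the edges and the score of each peak, so length and score are not separate measures. The relation may come from the calling itself and decides nothing about CNC binding.

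**Figure D2:**
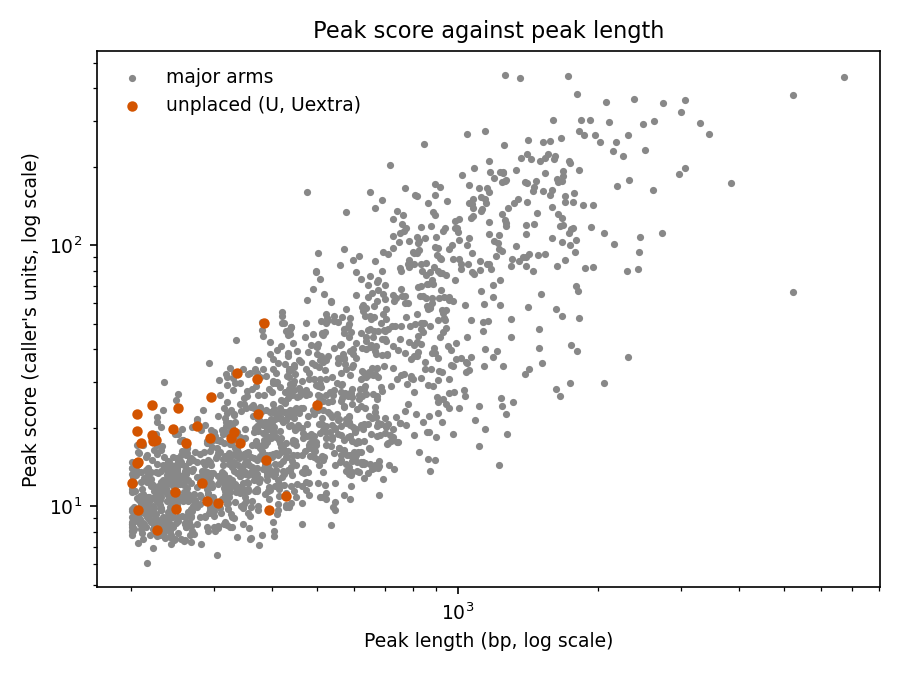
Each point is a peak, with its length in bp on the x axis and the authors' score on the y axis, both on log scales. Grey points are the 1641 peaks on the major arms and orange points the 34 peaks on unplaced sequences, which stay at or below 499 bp and a score of 50.22.

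The 5 major arms held 1641 peaks, or 97.4% of the list. There were 295 peaks on 2L, 341 on 2R, 308 on 3L, 387 on 3R and 310 on X. Arm 2R was the densest, with 17.7 peaks per Mb between its first and last peak against 13.9 per Mb over the other 4 arms. This is a ratio of 1.27 (permutation test, Benjamini-Hochberg adjusted p = 0.0004 over the 5 arms). The X chromosome, with 14.8 peaks per Mb against 14.5 on the autosomal arms, did not pass the test (permutation, adjusted p = 0.69), nor did 2L, 3L and 3R. The 2R test takes peaks as independent, and with peaks closer than 5 kb joined the ratio was 1.21 (permutation, adjusted p = 0.06). The span on 2R starts at 1854437, and with spans counted from position 1 of each arm the ratio was 1.17 (permutation, adjusted p = 0.061).

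The highest scores were scarce on 3L. A score above 200 was reached by 2 of 308 peaks on 3L (0.65%) and by 46 of 1333 on the other arms (3.45%), an odds ratio of 0.18 (Fisher's exact test, p = 0.0046, adjusted p = 0.046 over 10 tests). Among the 842 highest-scoring peaks the adjusted p was 0.063 (exact test, odds ratio 0.19), and among the 421 highest 0.077 (exact test). With peaks joined it was 0.025 to 0.043 (exact test). Both score filters keep every peak above 200, so only the number of lower-scoring peaks changed. Joined peaks keep their highest score. These settings are therefore no separate check of the scarcity on 3L. The highest score on 3L was 215.58. Above a score of 100, 3L held 29 peaks (9.42%) against 11.2% on the other arms, which did not pass Fisher's exact test (adjusted p = 0.6). Median scores of the arms ran from 19.1 on X to 20.9 on 3R, and median lengths from 418.5 bp on 3L to 472 bp on 2R. None of these 10 medians passed a test against the other arms (permutation test, adjusted p from 0.55 to 0.70).

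CNC peaks lay in groups along every arm. The median distance between neighbouring centres was 24.2 kb, against 47.6 kb (central 95% of placements 45.1 to 49.7 kb) for the same peaks placed at random, a ratio of 0.51 (permutation p = 0.002, the smallest possible). Peaks were closer than random on each of the 5 arms, with ratios from 0.46 on X to 0.65 on 3L (permutation test, adjusted p = 0.002 on each). Of all neighbours, 27.3% had centres within 5 kb, against 7.03% in random placements, an excess of 3.89 times that was 2.22 times with peaks closer than 1 kb joined. At the other end, the longest interval between neighbouring peaks was 985 kb on 2L, from 15271880 to 16257119. The ends of the arms were left out of this measure, and the first peak on 2R began only at 1854437. With peaks closer than 20 kb joined, which removes all shorter distances, the ratio was 0.99 (permutation p = 0.79).

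**Figure D3:**
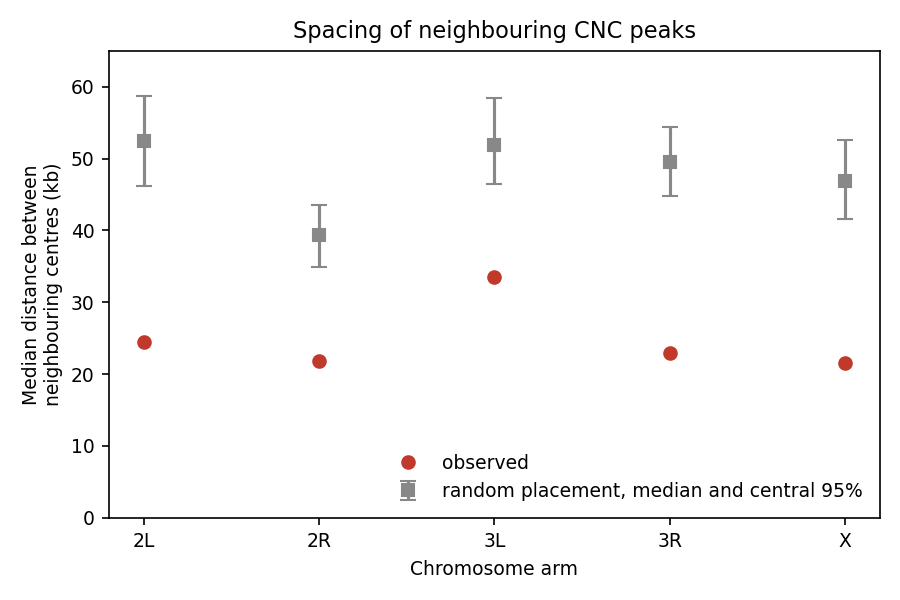
Median distance between neighbouring peak centres in kb (y axis) on each major arm (x axis). Red points are the observed values, from 21.5 kb on X to 33.6 kb on 3L; grey squares and bars are the median and central 95% of 1000 random placements, all of which lie above the observed points of their arm.

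A pair of stretches was denser than the spacing of their own arm gave. On 2L, 17 peaks lay between 16448329 and 16541286, with a median score of 16.6 and including the site that scored 364.3. Shuffling the distances between neighbours on 2L gave a densest window with a median of 10 peaks (permutation p = 0.003, adjusted p = 0.015 over the 5 arms). On 2R, 16 peaks lay between 14239245 and 14333417, with a median score of 13.6 and a highest score of 166.49, against a shuffled median of 11 peaks (permutation, adjusted p = 0.025). The densest windows on 3R, with 12 peaks, on 3L, with 11, and on X, with 10, did not pass this test. The test was not repeated with close peaks joined.

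Few CNC peaks lay outside the major arms. Chromosome 4, the small and largely heterochromatic autosome, held 5 peaks between 328608 and 997643, with scores from 8.55 to 28.93. The assembled heterochromatic sequences held 4 peaks, 1 on 2LHet, 2 on 2RHet and 1 on XHet, with scores from 8.03 to 32.85. The unplaced sequences U and Uextra held 34 peaks, 2.02% of the list (exact 95% interval 1.40 to 2.81%). Peaks on unplaced sequences were shorter than those on the arms, with medians of 269.5 and 446 bp (permutation test, adjusted p = 0.031). The difference, -176.5 bp, was -402 bp among the 842 highest-scoring peaks, of which 11 were unplaced. Their median scores, 17.9 and 20.0, did not pass that permutation test (adjusted p = 0.52), nor did the difference of -18.3 among those 842 peaks (permutation p = 0.17).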

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

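The 5 peaks of chromosome 4 aside, 38 peaks lay on unplaced or heterochromatic sequences and entered none of the tests of position on the arms. They are given here because a signal appeared in a part of the data outside those tests. The tests in this part were chosen after seeing the data, except that the prediction for the length of peaks of like score was written before its result.

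Of these, the 34 peaks on U and Uextra had a median length of 269.5 bp against 446 bp on the arms. Lower scores do not account for this, since within twentieths of the score the unplaced peaks were still shorter by a median difference of -110 bp (permutation p = 0.0011). A candidate explanation is a flat background estimate where input reads are few, which would give many peaks the same score. A score shared with another peak was held by 61.8% of the unplaced peaks, against 47.1% with labels shuffled within twentieths of the score (permutation p = 0.065), so this stays open with 34 peaks. The sequence content of these regions was not analysed here, and no biological explanation was tested.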

How the results depend on the processing

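No paired analysis was possible because the list holds no values of single libraries, and for the same reason no replicate could be left out. The stricter lists held the 842 and the 421 highest-scoring peaks by construction. The 2R density ratio, 1.27 as deposited, lost its call with peaks closer than 5 kb joined (1.21), with peaks closer than 20 kb joined (1.22) and with spans from position 1 (1.17), and kept it in the other 4 settings; the cause was not tested. The spacing ratio lost its call only with peaks closer than 20 kb joined (0.990), where the joining itself removes short distances, and was 0.50 to 0.81 in the other 6. The correlation of length and score stayed between 0.62 and 0.83 over 6 settings. Of the 4 arms whose density did not pass the test as deposited, 2L stayed below 1 and the others changed side. Arm 3L went to 1.03 at 20 kb, and 3R to 1.02 and 1.06 among the top 842 and 421. The X ratio went to 0.939 among the top 842, 0.994 at 1 kb and 0.977 at 20 kb. With sequence under peaks in place of peak number, 3L was at 0.78 of the other arms and passed the test (permutation of 1000 redraws, adjusted p = 0.005). The cause was not tested. Promoter, gene feature, motif and gene list alternatives were not run, nor were placement along whole arms and arm densities over all sequences. Without read counts, the limit that depth sets on weak sites is unknown.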

Other observations

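The tests in this part were chosen after seeing the data, though the predictions for placement within occupied bins, alone and with joined peaks, were written before their results. The second densest stretch on 2L lay past the first, which ended at 16541286. It held 13 peaks between 16792612 and 16886659, with a highest score of 84.83. Against the densest window of shuffled distances on 2L it did not pass (permutation p = 0.077, not adjusted).

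The grouping of peaks along the arms, a spacing ratio of 0.51, was set against 2 technical explanations. Splitting of one bound region by the caller is not the whole of it, since the ratio was 0.81 (permutation p = 0.002) with peaks closer than 5 kb joined, and neither are long stretches without any peak, since placement only in the 684 of 1133 bins of 100 kb that hold a peak gave 0.80 (permutation p = 0.002). Joining removes short distances and the bins were picked for holding peaks, so both steps raise the ratio by themselves. How much of each change the explanations account for is therefore not known. Both together gave 1.14, with the 5 kb minimum kept in the random placements. This met the outcome written beforehand for the 2 explanations together, a ratio of 1 or more. That outcome decides nothing, since simulated peaks without grouping, which were not part of the prediction, met it too. Because the bins were picked for holding peaks, ungrouped simulated peaks gave 1.24 by that measure (1.16 to 1.29 over 100 runs). The observed value lay below all 100 runs, towards grouping (permutation p = 0.02 from these placements, the smallest possible), but those runs hold no long empty stretches, so whether both together account for the grouping stays open. Gene density, open chromatin and CNC itself also stay open and were not tested.

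Neighbours under 1 kb apart, 261 pairs by their edges, had unlike scores, with a Spearman's rho of -0.18 (permutation p = 0.0032). A peak with close neighbours on both sides enters more than 1 pair. The tests on pairs in this paragraph take pairs as independent, so their p-values may be too small. Among the 421 highest-scoring peaks, which left 11 such pairs, rho was -0.19 and did not pass the test (permutation p = 0.58). With distance measured from centres, 151 pairs gave a rho of -0.29 (permutation p = 0.00021). That limit leaves out pairs of long peaks, and longer peaks had higher scores. It therefore favours a negative rho by itself, and this value adds no separate evidence of unlike scores. Members of a pair by edges differed by a median of 35.3 percentile ranks of score. Pairs drawn at random from all arm peaks gave 29.3 (random draws, p = 0.0048), and the same peaks shuffled between pairs 29.4 (permutation p = 0.0029). By centres the median was 30.3, which did not pass against random pairs at 29.3 (random draws, p = 0.36) but did against shuffled pairs at 24.7 (permutation p = 0.009). These differences restate the negative rho over the same pairs and so decide nothing about its source. Whether some of these neighbours are side peaks of a stronger peak stays open. Examples are the peaks of 7.4 and 13.74 beside the sites that scored 361.04 and 364.3.

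Some scores were repeated: the 1684 peaks had 1289 distinct scores, and 615 peaks (36.5%) shared theirs with another, up to 10 times for 5 of the values. Scores are given to 2 decimals, and how many repeats such rounding gives by itself was not tested.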
